A study of Rattus norvegicus with 12 samples.

How the data were processed

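RNA from rat joint tissue was measured in 12 libraries, 4 each labelled sham, model and treatment. Per the labels, RNA was extracted with Trizol and libraries were made with the VAHTS Universal V5 kit. Per the submitters' processing notes, the tools were fastp and DESeq2, for which no versions are given, and the genome build was mRatBN7.2. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here, so reads of antisense genes and of near-identical gene families cannot be assigned with certainty.

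The authors deposited 3 full tables of 8 libraries each, 1 per comparison, and 3 tables of changed genes. Expression values in the deposited tables are a normalised signal, in which each library's gene read counts are divided by 1 size factor set within that table. Read off the values, every entry of a library is a whole multiple of 1 step (100% of values at a tolerance of 0.001 reads), so whole reads were recovered. Reads of treatment 3 were taken from the treatment against sham table alone, since its step in the other is close to 1. For the other 11 libraries, genes in both tables that hold a library differed by 0 reads. The authors' fold changes in the deposited tables are on a log2 scale, and the deposited p-value columns hold the authors' p and adjusted p, with adjusted p set to 1 for untested genes. The authors' fold changes and p-values serve only for the description of the authors' lists. A single line of each full table was emptied for this work and is not used here. Gene models, symbols and coordinates are those of the authors' tables. Of the gene IDs, 3877 had no symbol there, 1252 with a blank name and the rest with an Ensembl ID as the name. A later rat annotation (GRCr8) named 0 of the 3877.

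Recovered reads summed to 15513116 to 17218402 per library, with group means of 16497938 in sham, 16026252 in model and 16761649 in treatment. A gene with 3 reads or fewer in a group is given as a ratio of reads per total with an exact 95% counting interval, which holds counting error only, in place of a fitted fold change.

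Before the data were examined, the comparisons, tests, gene lists, rule for named genes and most alternatives were written down. That design planned edgeR on all 12 libraries, with limma in case the files held normalised values. Because they do, with size factors set per table, each comparison was tested with limma 3.58.1 in R 4.3.3 within its own table of 8 libraries (moderated t test with trend and robust options) on log2(value + 1), for genes with a mean value of at least 1. Fold changes are differences of group means on that log2(value + 1) scale, which shrinks them for low values, ± the SE of the limma fit. Adjusted p is the Benjamini-Hochberg false discovery rate of limma over all genes tested, called at 0.05, and the adjusted p of a gene without a tool named is from limma. Data were simulated with the mean reads of each comparison and 100 changed genes of each size. limma recovered 69.0%, 54.0% and 65.0% of 4-fold changes for model against sham, treatment against model and treatment against sham, and 7%, 3% and 7% of 2-fold changes. The spread of each gene was estimated once over all 12 libraries, so it was not that of the single comparison. Genes varied independently, and changed genes were drawn only from those with more reads. False calls were 6 of 82, 7 of 64 and 5 of 77. A change missed at this size is therefore not excluded.

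The 45 gene lists fixed beforehand, of which 18 mark cell types, cover joint matrix and its enzymes, inflammation, cell types that a joint piece can hold, signalling, stress and metabolism. They hold 876 genes, of which 847 were matched by symbol and 29 were not. Each list was tested within a comparison with camera of limma (preset correlation between genes of 0.01), adjusted over the lists, and again with an estimated correlation and with fry of limma. Members past the test were counted with adjustment over all genes and over the list alone. Cell-type lists were scored per library as the mean log2 CPM of members on recovered reads (prior count 2, scaled to library totals), centred per gene over the 12 libraries, and groups of 4 were compared with an exact permutation test over 70 assignments, adjusted over 18 lists. The smallest p of this permutation test is 0.0286, so its adjusted p turns on how many lists reach that floor.

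Genes were named by a fixed rule. Per comparison it takes the 8 highest and the 8 lowest log2 fold changes among genes past the test with a mean log2 CPM of at least 1, groups that do not overlap and a usual symbol. Where fewer than 5 genes passed, it takes the 5 smallest p in each direction. From each list past camera, or with at least 3 members past the test, it takes the 2 members with the smallest p, and it always takes 9 standard osteoarthritis readouts. It gave 56, 78 and 94 genes in the 3 comparisons, apart from some genes that are not reported here, and others are left out of the text for length. Hba-a1 and Fn1 were named after their values were seen. Reversal was counted as genes past the test in model against sham and past it with the opposite sign in treatment against model. Its correlation and covariance were set against 20 simulations without effects that share the model libraries.

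Alternatives were pseudocounts of 0.1 and 5, no filter and a mean value of at least 5, a requirement of 2-fold change, the replicate number as a block, the muscle or marrow score as a covariate, each library left out in turn, DESeq2 1.42.0 and limma-voom with sample quality weights. Chosen after seeing the files were edgeR 4.0.16 quasi-likelihood tests on recovered reads (TMM, other factors, other filters, 2 groups only, block), values rescaled by TMM, a fit without the 3 libraries richest in muscle transcripts, and a fit without members of the blood-cell and muscle lists.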

Results

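RNA from rat joint tissue was sequenced in 12 libraries, 4 labelled sham, 4 labelled model and 4 labelled treatment. The series title names knee osteoarthritis, in which cartilage of the joint is lost, and acupuncture at points around the knee. The labels give the groups no further description, so how the model was made and what the treatment libraries received beyond the title are not stated. They also do not say that the replicates are separate animals, so p-values measure the spread between these samples, which may be technical, as in the dissection. Libraries of a group differed by more than counting noise (chi-square per degree of freedom of 18.6 to 342). Each library held 15513116 to 17218402 reads assigned to genes, and 23144 genes were listed in at least 1 of the authors' tables.

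The most abundant transcript differed between groups. In all 8 sham and model libraries it was Hba-a1, an alpha-globin of red blood cells, at 3.12% to 6.22% of reads, and in all 4 treatment libraries it was Fn1, fibronectin of the extracellular matrix, at 1.38% to 4.79%. Across 16358 genes, the first principal component held 56.5% of the variance and took values of 0.37 to 0.40 in the treatment libraries and -0.31 to 0.08 in the others. The second held 16.1% and was highest in treatment 2, sham 2 and sham 4, the 3 libraries with the highest skeletal muscle scores. A score here is the mean log2 CPM of a list's genes, each centred over the 12 libraries.

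**Figure D1:**
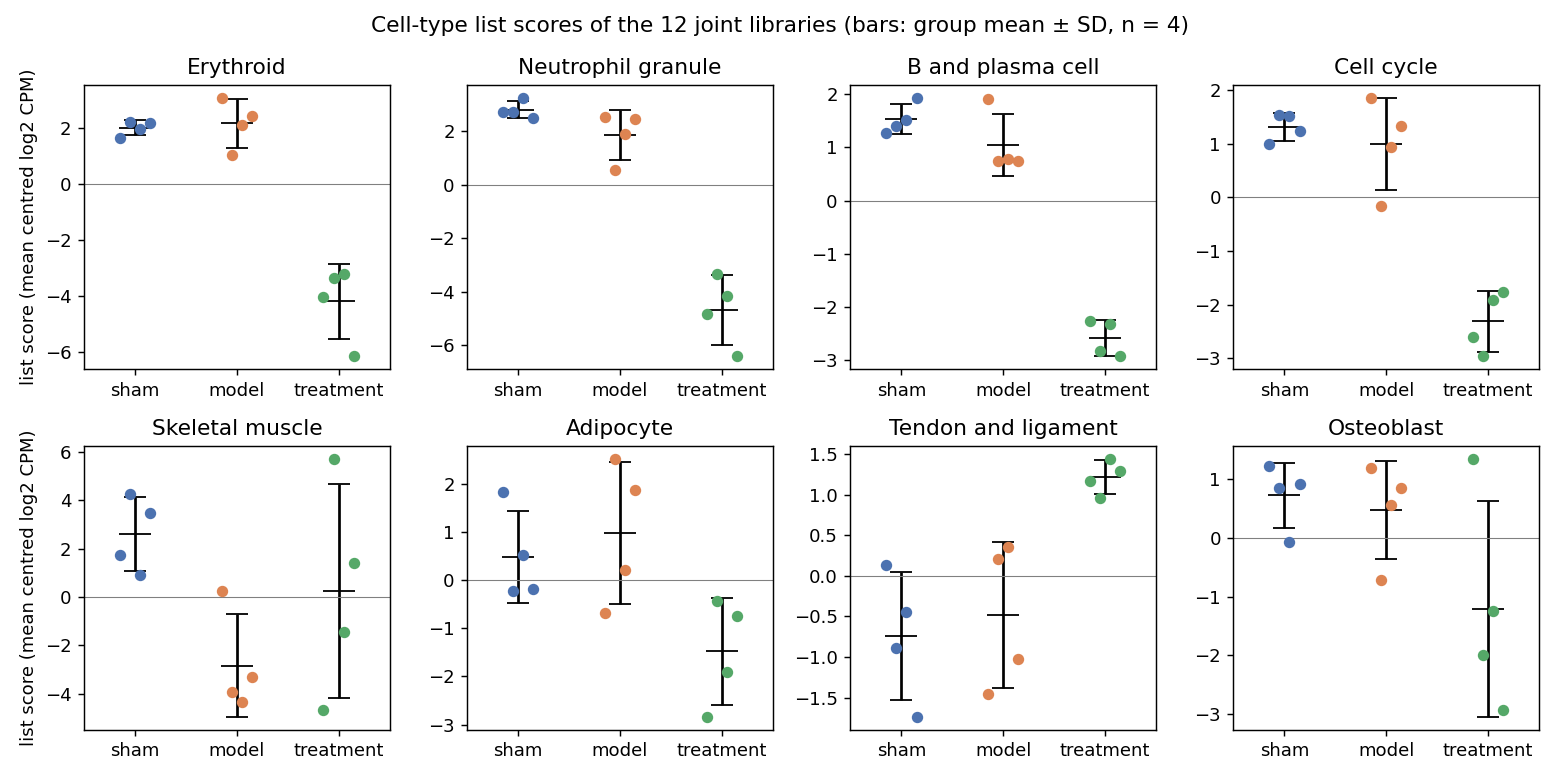
Scores of 8 cell-type gene lists in each library (mean log2 CPM of the members, centred per gene over the 12 libraries), with points for the 4 libraries of each group and the mean ± SD. The erythroid mean was -4.20 ± 1.35 in treatment against 2.02 ± 0.27 in sham and 2.18 ± 0.86 in model, and muscle scores spanned -4.69 to 5.72 within the treatment group.

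Model against sham asks what the osteoarthritis model changed in the joint. The largest difference lay in skeletal muscle genes, which were lower in model as a list, while vascular, collagen and matrix-enzyme lists were higher and neutrophil genes lower, lists with adjusted p = 0.726 to 0.787 with an estimated correlation. No single gene passed the test. The muscle list, of contractile and calcium-handling proteins, had a median log2 fold change of -5.63 over 26 measured members, and 23 were lower when adjusted over the list alone, against 0 over all genes tested. For this list camera gave adjusted p = 6.31e-26, and adjusted p = 0.726 with an estimated correlation. Myh4, a fast-fibre myosin heavy chain (ENSRNOG00000049695, chromosome 10, 51885913 to 51946295 in mRatBN7.2), differed by -8.07 ± 1.30 (log2 fold change ± SE on the log2(value + 1) scale, n = 4 per group, limma adjusted p = 0.203). Its normalised value was 416 ± 663 in model and 81054 ± 72445 in sham (SD). Atp2a1, the calcium pump of the muscle reticulum, differed by -7.58 ± 1.24 (adjusted p = 0.203).

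The muscle score was -2.84 ± 2.11 against 2.59 ± 1.54 in sham (exact permutation p = 0.0286, the smallest that 70 assignments allow, and 0.514 after adjustment over 18 cell-type lists). Single libraries ranged from 0.91 to 4.27 in sham, and model 1, at 0.27, lay apart from the other model libraries at -4.36 to -3.32. None of the 18 scores passed after adjustment, which 1 list alone cannot do at that smallest p. Genes of energy metabolism were lower together with the muscle score. Oxidative phosphorylation had a median of -0.48. Adjusted over the list alone, 18 of 29 members were lower, against 0 over all genes. The list had camera adjusted p = 9.60e-13, and adjusted p = 0.763 with an estimated correlation. Its members with the smallest p were Cox6a2 (-6.10 ± 1.44), the muscle form of a cytochrome c oxidase subunit, and Ndufb8 (-0.53 ± 0.11) of complex I. Glycolysis had a median of -0.44, with 9 members lower and 1 higher when adjusted over the list alone and 0 over all genes. Its camera result was adjusted p = 0.000184, and adjusted p = 0.162 with an estimated correlation. Pkm (-0.94 ± 0.16) and Ldha (-1.03 ± 0.19), which carry the last steps from glucose to lactate, had the smallest p there. With the muscle score as a covariate Cox6a2 was at 0.83. Every model library lies below every sham library in that score, so this covariate shares much of its information with the groups. A change of sign under it does not show that muscle content is the cause.

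Matrix lists were higher in model, at medians of 1.02 for fibrillar collagen and fibrosis genes, 0.68 for matrix-degrading enzymes, 0.78 for protease inhibitors, 0.67 for synovial fibroblast markers and 0.32 for TGF-beta and BMP genes. For these lists camera gave adjusted p = 8.39e-07 to 0.0398, and adjusted p = 0.763 with an estimated correlation. Members with the smallest p were Plod2 (0.96 ± 0.23), a collagen lysyl hydroxylase, Ctsb (0.97 ± 0.25), cathepsin B, and Mmp12 (3.62 ± 1.08), macrophage elastase. Timp1 (1.23 ± 0.43), Pdgfrb (0.99 ± 0.38) and Tgfbr2 (0.68 ± 0.25) had among the smallest p of the other lists. Fibrillar collagen scores were -1.36 in model 1 and -0.22 to 0.73 in model 2 to 4, against -1.54 to -0.19 in sham. With the muscle score as a covariate, Mmp12 (-0.58), Timp1 (-0.36), Pdgfrb (-0.42) and Tgfbr2 (-0.22) changed sign, in a fit where score and group are hard to separate. Vessel lists were higher too, at medians of 1.29 for smooth muscle, 0.79 for endothelium and 0.59 for angiogenesis. These lists had camera adjusted p = 8.65e-05 to 0.0146, and adjusted p = 0.763 to 0.787 with an estimated correlation. Examples were Emcn (0.95 ± 0.35) and Kdr (0.64 ± 0.25), both of endothelial cells, and Smtn (0.77 ± 0.29). Des, desmin, which skeletal muscle makes too, was lower (-1.72 ± 0.69). The same covariate turned Emcn (-0.24), Kdr (-0.0278) and Des (0.0336). The smooth muscle score was 2.22 in model 2 and -1.97 in model 1, so it spread more within the model group than between the groups. No member of these 8 lists passed over all genes or when adjusted over the list alone.

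Immune lists split by direction. Complement (median 0.59), macrophage markers (0.41) and interferon-stimulated genes (0.33) were higher. Camera gave these lists adjusted p = 0.00556 to 0.0469, and adjusted p = 0.763 to 0.787 with an estimated correlation. Of the interferon-stimulated genes 3 were higher when adjusted over the list alone, against 0 over all genes. Vsig4 (2.35 ± 0.62), a complement receptor of resident macrophages, and Ifi44l (1.43 ± 0.27) had the smallest p of their lists, while Lyz2, a lysozyme of macrophages and neutrophils, was lower (-0.85 ± 0.31). Neutrophil granule genes had a median of -0.92, B cell genes -0.35, cell cycle genes -0.32 and ribosomal protein genes -0.18. For these lists camera gave adjusted p = 1.0e-07 to 0.0158, and adjusted p = 0.763 to 0.825 with an estimated correlation. Among them were Retnlg (-1.70 ± 0.53), Elane (-0.83 ± 0.27), neutrophil elastase, Cd22 (-0.90 ± 0.20), a B cell receptor inhibitor and the 1 B cell gene lower when adjusted over the list alone, Mcm5 (-0.72 ± 0.38) and Rps9 (-0.34 ± 0.13). The neutrophil score was 1.87 ± 0.93 against 2.81 ± 0.32 in sham, and 0.55 in model 2. Immediate early genes (0.57), steroid and stress response genes (0.47) and mitochondrially encoded genes (0.39) were higher. These lists had camera adjusted p = 0.00840 to 0.0433, and adjusted p = 0.763 to 0.809 with an estimated correlation. Klf6 (0.82 ± 0.26), Sgk1 (0.55 ± 0.17) and Mt-nd4l (0.68 ± 0.49) were among their members with the smallest p. With the muscle covariate Mcm5 (0.14) and Klf6 (-0.17) changed sign. Averages of 4 lists that did not pass camera differed in sign: skin genes had a median of 0.22 and a mean of -0.16, lymph node genes -0.25 and 0.18, pain genes -0.0906 and 0.11, and NF-kB genes -0.0202 and 0.00899.

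Of 20205 genes tested with limma, 0 passed a false discovery rate of 0.05, 2618 had an unadjusted p under 0.05 and the smallest adjusted p was 0.203. edgeR on the reads recovered from the values called 0 (2154 at unadjusted p under 0.05). DESeq2 called 288 (171 higher, 117 lower) and limma-voom with quality weights 817 (571 higher, 246 lower). Leaving out model 1 gave 169 genes (64 of them higher), leaving out sham 3 gave 28 and leaving out model 4 gave 2. Of the 56 named genes 27 passed in at least 1 alternative, 24 with limma-voom, 16 with DESeq2, 13 without model 1 and 6 without sham 3. The genes with the smallest p, none past the test in limma on all 8 libraries, were higher for Dtx3l (1.11 ± 0.16), a ubiquitin ligase, Dhrs7l1 (3.54 ± 0.59) and Cttnbp2nl (1.17 ± 0.21). They were lower for Dmrt2 (-4.62 ± 0.68), a transcription factor of developing muscle and skeleton, and Myh4. The others were near 0 reads in a group. Asb16 had 1 read in model and 380 in sham (sham higher by a ratio of 369, 95% counting interval 65.9 to 14618). Lbx1, a homeobox gene of limb muscle precursors, had 2 and 274 (133, 36.5 to 1104). Barx2 had 2 and 60 (29.1, 7.72 to 246). Hoxa11-as had 108 reads in model and 2 in sham (model higher by a ratio of 55.6, 15 to 465). Reads of this antisense gene and of its partner cannot be told apart when the use of strand in counting is not stated. An unnamed gene model on chromosome 10, positions 81229367 to 81230568, had 32 and 1 (32.9, 5.50 to 1341).

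All 21 lists past camera in this comparison were called with a preset correlation of 0.01 between genes, and 0 held with an estimated one. The rotation test fry, which asks whether a list's genes move one way on balance, called 1, glycolysis (adjusted p = 0.00425). Leaving out 1 library ended the camera calls of some lists, given with the adjusted p: macrophage (0.0785 to 0.449 without model 3, 4 or sham 2, 4), B cell (0.0712 to 0.122 without model 4 or sham 4), smooth muscle (0.0732 without model 2) and TGF-beta and BMP (0.0501 to 0.168 without model 2, 3 or sham 2, 3, 4). Mitochondrially encoded (0.0712 to 0.589 without model 2, 4 or sham 1, 3), cell cycle (0.0663 to 0.822 without model 2 or sham 2, 3), steroid and stress response (0.0651 to 0.338 without model 3 or sham 2, 3) and angiogenesis (0.0508 to 0.148 without model 2 or sham 2) lost the call as well. Without sham 2 and sham 4, the libraries of this comparison among the 3 richest in muscle transcripts, 12 lists passed.

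The 9 standard osteoarthritis readouts did not pass in model against sham. Mmp3, stromelysin 1, differed by 2.96 ± 0.90 (adjusted p = 0.306) and Prg4, the joint lubricant lubricin, by 2.29 ± 1.08 (adjusted p = 0.408). Differences for the others were -0.99 ± 1.30 for Col2a1, 0.67 ± 0.52 for Acan, 0.68 ± 0.52 for Mmp13, 0.59 ± 0.43 for Adamts5, -0.34 ± 0.32 for Il1b, 0.97 ± 0.98 for Il6 and 0.03 ± 0.53 for Tnf, with adjusted p of 0.563 to 0.981. Signs were not stable. Col2a1 was at 0.12 with edgeR, 0.12 with DESeq2 and 0.53 without model 2, and Tnf at -0.30 without model 1. With the muscle covariate Col2a1 was at 1.63, Adamts5 at -0.89, Il1b at 0.49, Il6 at -1.56 and Prg4 at -0.54. On data simulated with the mean reads of this comparison, but a spread estimated over all libraries, limma recovered 69.0% of genes changed 4-fold. It recovered 7% of those changed 2-fold, so a change of the smaller size would mostly be missed.

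**Figure D2:**
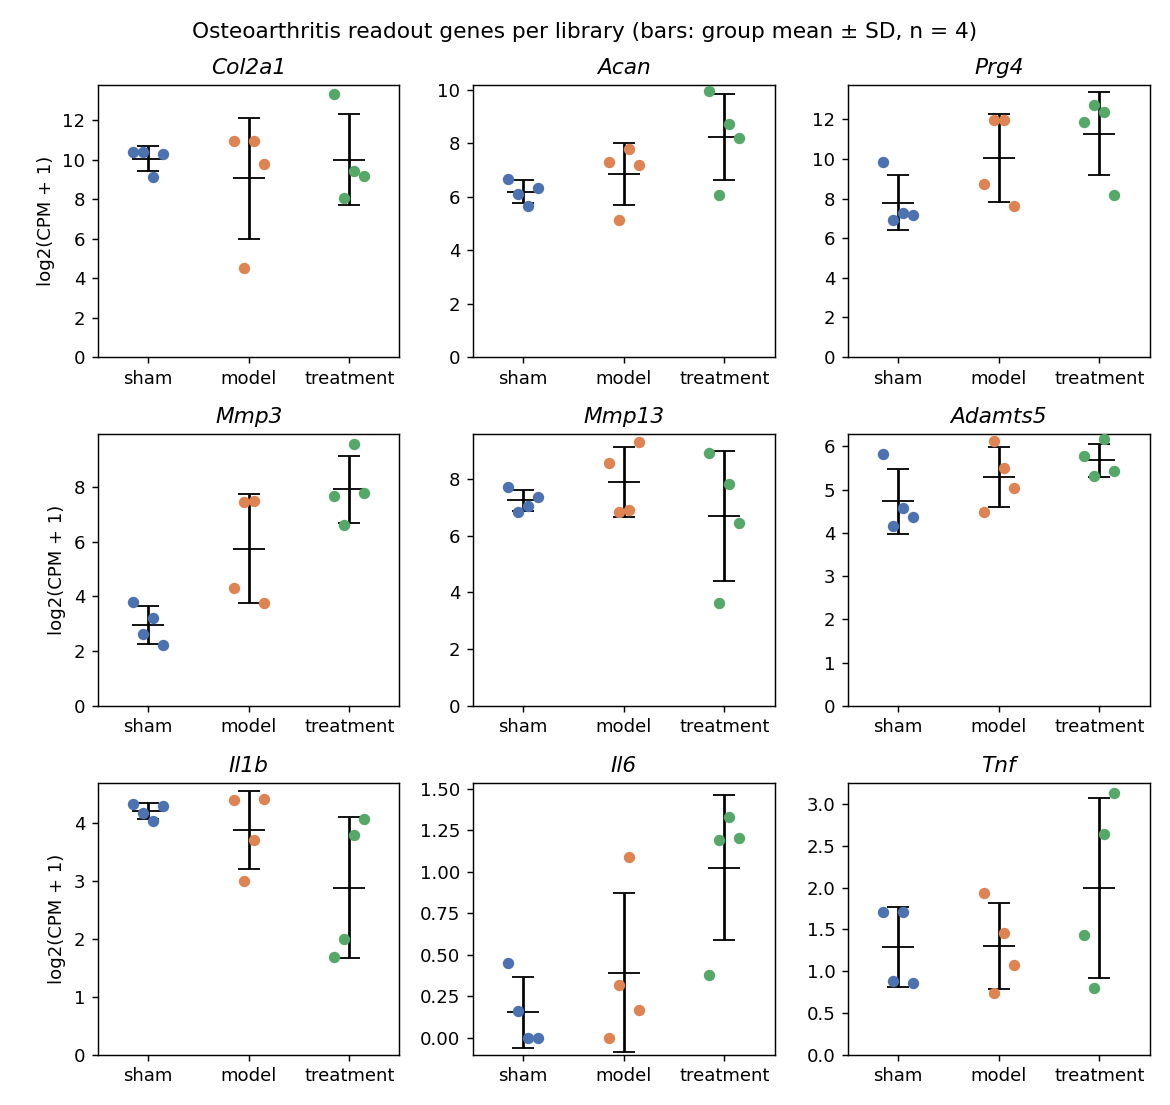
Levels of the 9 osteoarthritis readout genes in each library as log2(CPM + 1), with points for the 4 libraries per group and bars for mean ± SD. Mmp3 had its highest group mean in treatment, and of its 3 comparisons only the treatment against sham difference of 5.30 passed the test.

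Treatment against model asks what the treatment changed in the joint. Genes of blood-forming marrow fell almost as whole lists, those of neutrophils, red cell precursors and B cells, together with cell cycle genes. All 18 erythroid genes, 17 of 18 neutrophil granule genes and 22 of 22 cell cycle genes fell, the same numbers when adjusted over the list alone, with medians of -6.40, -6.92 and -3.29. Camera gave these lists adjusted p = 1.85e-17 to 2.43e-14, and adjusted p = 0.332 to 0.433 with an estimated correlation. B cell genes fell in 13 of 16 members, 14 when adjusted over the list alone (median -3.82, camera adjusted p = 2.43e-11, adjusted p = 0.237 with an estimated correlation). Members of the collagen matrix (4 of 24), tendon (4 of 10) and clock lists (8 of 18) rose, lists with adjusted p = 0.447 to 0.678 with an estimated correlation.

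Prg2, the major basic protein of eosinophil granules (ENSRNOG00000008394, chromosome 3, 70062535 to 70066101), fell by 9.66 ± 1.44 (adjusted p = 0.00429), from a normalised value of 14799 ± 12553 in model to 38.9 ± 61.8 in treatment (SD, n = 4). Its relative Prg3 fell by 9.05 ± 1.32, and whether reads were split between related genes in counting was not tested. Cd177, a neutrophil surface protein (ENSRNOG00000022669, chromosome 1, 80340034 to 80360621), fell by 9.64 ± 1.22 (adjusted p = 0.00246). Ngp (-9.05 ± 1.30), Mmp8 (-8.24 ± 1.11), the neutrophil collagenase, Ctsg (-7.95 ± 1.52) and both subunits of calprotectin, S100a9 (-8.14 ± 1.04) and S100a8 (-8.04 ± 0.99), completed the 8 lowest (limma adjusted p = 0.00219 to 0.0115). Further examples were Cxcr2 (-5.33 ± 0.53), Alas2 (-5.63 ± 0.58), the first enzyme of haem synthesis in red cells, Trim10 (-6.23 ± 0.52) and Cd79a (-5.15 ± 0.43) of the B cell receptor. Fcrla (-4.29 ± 0.36) fell too, as did Mki67 (-4.16 ± 0.47) and Top2a (-3.83 ± 0.43), both of dividing cells (limma adjusted p = 0.000944 to 0.00196 for these 7). The erythroid score was -4.20 ± 1.35 against 2.18 ± 0.86 in model and the neutrophil score -4.68 ± 1.30 against 1.87 ± 0.93 (exact permutation p = 0.0286 each, adjusted p = 0.0735), with all 4 treatment libraries below all 4 model libraries.

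Members of other lists fell with the marrow scores. Mast cell genes fell in 5 of 9 members (6 adjusted over the list alone), among them Hdc (-3.74 ± 0.47), which makes histamine, and Ms4a2 (-4.35 ± 0.55). T and NK cell genes fell in 2 of 21 (2 adjusted over the list alone), the cytotoxic genes Nkg7 (-5.51 ± 0.44) and Ncr1 (-4.59 ± 0.88). Adipocyte genes fell in 5 of 17 (11 adjusted over the list alone), with Cfd (-2.17 ± 0.39) and Retn (-4.16 ± 0.83). Osteoblast genes fell in 1 of 19 (0 adjusted over the list alone), Sost (-4.56 ± 1.29), a Wnt inhibitor of osteocytes. These 4 lists passed camera. For these lists camera gave adjusted p = 0.000117 to 0.0427, and adjusted p = 0.332 to 0.787 with an estimated correlation. The interferon-stimulated list fell in 9 of 22 members (12 adjusted over the list alone, median -0.96). For this list camera gave adjusted p = 1.22e-05, and adjusted p = 0.472 with an estimated correlation. Leading it were Rsad2 (-5.95 ± 0.45), viperin (ENSRNOG00000007539, chromosome 6, 43047658 to 43059699), and Ifit1 (-3.69 ± 0.49). From lists that did not pass camera, Cr2 (-4.73 ± 0.56), a complement receptor of B cells, fell. So did Nlrc4 (-2.61 ± 0.55) and Casp8 (-0.92 ± 0.20) of inflammasome and cell death pathways, Gclm (-2.08 ± 0.25) of glutathione synthesis, Cat (-1.13 ± 0.23), catalase, Birc5 (-3.23 ± 0.42) and Scd (-3.07 ± 0.70). By contrast Cdkn1a (2.55 ± 0.32), the cell cycle inhibitor p21, and Insig1 (0.96 ± 0.20) rose. The antioxidant list, with a median of 0.02 and a mean of -0.08, had 3 members higher and 4 lower.

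Some members of the matrix lists that passed camera rose while the marrow scores fell. The cartilage matrix list did not pass camera (adjusted p = 0.0957), with 1 of 25 members higher and 1 lower (0 and 0 adjusted over the list alone). In the others, counts past the test were 4 of 24 (16 adjusted over the list alone) for fibrillar collagen and fibrosis, 2 of 10 (5 adjusted over the list alone) for protease inhibitors and 4 of 10 (9 adjusted over the list alone) for tendon and ligament. They were 5 of 23 (10 adjusted over the list alone) for matrix-degrading enzymes, where 2 fell, 2 of 16 (3 adjusted over the list alone) for synovial fibroblast, where 1 fell, and 3 of 25 (4 adjusted over the list alone) for TGF-beta and BMP. These lists had camera adjusted p = 1.44e-06 to 0.0154, and adjusted p = 0.447 to 0.717 with an estimated correlation. Tnn, the matrix glycoprotein tenascin N (ENSRNOG00000002548, chromosome 13, 72319155 to 72408156), rose by 3.68 ± 0.96 (adjusted p = 0.0382), with a normalised value of 16084 ± 10545 in treatment and 2384 ± 3175 in model. Msln, mesothelin (ENSRNOG00000019445, chromosome 10, 14771961 to 14777643), rose by 3.62 ± 0.66 (adjusted p = 0.00927). C1qtnf3 (3.51 ± 0.94), Stmn2 (3.14 ± 0.90) and Rab15 (3.13 ± 0.75) rose too. Kera (3.09 ± 0.82), the small proteoglycan keratocan, and an unnamed gene model on chromosome 4, positions 502658 to 509834 (3.29 ± 0.58), were among the 8 highest as well (limma adjusted p = 0.00814 to 0.0496 for these 5). List members included Postn (2.81 ± 0.60), periostin, P4ha1 (1.39 ± 0.33), a collagen prolyl hydroxylase, Timp1 (1.90 ± 0.45), Timp2 (1.73 ± 0.47) and Thbs4 (2.53 ± 0.41). Others were Scx (2.28 ± 0.43), the tendon transcription factor scleraxis, Mmp11 (2.24 ± 0.33), Pdgfra (1.67 ± 0.38), Pdpn (2.11 ± 0.55), Chrd (1.25 ± 0.31) and Skil (0.65 ± 0.18). The Wnt list did not pass camera. Its 2 of 27 members that rose were Sfrp4 (2.97 ± 0.76) and Dkk3 (2.44 ± 0.68), while 1 fell (0 and 0 adjusted over the list alone). The tendon score was 1.22 ± 0.21 against -0.48 ± 0.90 in model (exact permutation p = 0.0286, adjusted p = 0.0735).

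Clock genes rose in 8 of 18 and fell in 1 (9 and 1 adjusted over the list alone), with Bhlhe40 (2.13 ± 0.20) and Bhlhe41 (2.67 ± 0.38), repressors that answer to the clock and to low oxygen. Glycolysis and hypoxia genes rose in 6 of 23 and fell in 1 (9 and 1 adjusted over the list alone), among them the glucose transporter Slc2a1 (2.0 ± 0.42) and Egln3 (1.5 ± 0.33). Autophagy genes rose in 4 of 21 and fell in 1 (7 and 1 adjusted over the list alone) with Sqstm1 (1.0 ± 0.17). Immediate early genes rose in 3 of 18 and fell in 1 (6 and 1 adjusted over the list alone) with Ier3 (1.31 ± 0.26), while Btg2 (-1.39 ± 0.18) fell. Camera gave these lists adjusted p = 8.00e-05 to 0.0120, and adjusted p = 0.237 to 0.691 with an estimated correlation. Complement divided, with 4 members higher and 3 lower (7 and 3 adjusted over the list alone), Cfp (-2.49 ± 0.44) and Cfd falling. Macrophage markers rose in 4 of 19 (4 adjusted over the list alone), with Cd14 (1.63 ± 0.40) and Trem2 (2.60 ± 0.70), a lipid-sensing receptor. For these lists camera gave adjusted p = 0.0280 to 0.0388, and adjusted p = 0.750 to 0.785 with an estimated correlation. The muscle list was higher by camera, at a median of 3.56. The list had camera adjusted p = 0.000486, and adjusted p = 0.787 with an estimated correlation. Of its members 0 of 26 passed over all genes or over the list alone (Tnni2 4.21 ± 1.45, adjusted p = 0.0861). Oxidative phosphorylation, at 0.37, likewise had 0 members past the test in either adjustment. Its camera result was adjusted p = 0.0427, and adjusted p = 0.812 with an estimated correlation. Muscle scores of the treatment libraries were -4.69, 5.72, -1.46 and 1.42.

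limma called 2870 of 20328 genes, 731 higher and 2139 lower (25.5% higher). edgeR on the recovered reads called 4121, of which 31.8% were higher, or 35.9% with upper-quartile factors (1544 higher, 2752 lower). DESeq2 called 5756 and limma-voom 6645. With the marrow score as a covariate limma called 0 genes (546 at unadjusted p under 0.05), a fit in which score and group carry nearly the same information. The share higher was 41.2% with DESeq2 and 47.2% with limma-voom, and 7.95% (93 genes) with limma without model 4, so it depends on the tool and on single libraries. Leaving out 1 library moved the count to 1170 without model 4, 1576 without treatment 3 and 1641 without model 1. It was 1801 without treatment 1, 1888 without model 3 and 1892 without treatment 4. Of the 78 genes the rule named, 64 passed, and 36 of these kept the call in every alternative that tested them, apart from the covariates and a 2-fold requirement. The block ended 5 of the calls, edgeR 3 and the muscle covariate 3. The marrow covariate ended all 64, of which 46 kept their sign. In some alternative 8 other named genes gained a call. Adjusted p without 1 library exceeded 0.05 for Tnn (0.0605 to 0.114 without treatment 1, 2, 3, 4 or model 1, 4), C1qtnf3 (0.0509 to 0.111 without treatment 1, 2, 3, 4 or model 4), Stmn2 (0.0779 to 0.127 without treatment 1, 2, 3, 4 or model 1, 4) and Rab15 (0.0532 to 0.0754 without treatment 1, 2, 3, 4 or model 1, 4). Kera (0.0521 to 0.0927 without treatment 1, 2, 3, 4 or model 1, 4), Timp1 (0.0513 to 0.0905 without treatment 1, 3, 4 or model 1, 4), Timp2 (0.0505 to 0.118 without treatment 1, 2, 3, 4 or model 4) and Postn (0.0551 to 0.0647 without treatment 3 or model 4) lost the call too. P4ha1 (0.0537 to 0.0808 without treatment 3, 4 or model 1, 4), Nlrc4 (0.0646 without model 4), Casp8 (0.0518 to 0.0715 without treatment 1 or model 1, 4) and Sost (0.0849 to 0.117 without treatment 2, 3, 4 or model 1, 3, 4) lost the call too. Pdgfra (0.0504 to 0.0810 without treatment 1, 3 or model 1, 4), Pdpn (0.0708 to 0.109 without treatment 1, 2, 3 or model 1, 4), Cd14 (0.0593 to 0.0985 without treatment 1, 3, 4 or model 1, 4) and Trem2 (0.0512 to 0.121 without treatment 1, 2, 3, 4 or model 1, 4) lost the call too. Retn (0.0538 without model 4), Sfrp4 (0.0515 to 0.105 without treatment 1, 2, 3, 4 or model 1, 4), Dkk3 (0.0542 to 0.111 without treatment 1, 3, 4 or model 3, 4) and Chrd (0.0707 to 0.0842 without treatment 1, 3, 4 or model 4) lost the call too. Skil (0.0506 to 0.129 without treatment 1, 3, 4 or model 1, 2, 3, 4), Cat (0.0562 without model 4), Ier3 (0.0519 without model 4) and Slc2a1 (0.0509 to 0.0575 without treatment 1, 3 or model 4) lost the call too. Egln3 (0.0553 to 0.0616 without model 3, 4), Insig1 (0.0600 without model 4) and Scd (0.0524 to 0.0798 without treatment 1, 3 or model 1, 4) lost the call too. Camera calls ended likewise for complement (0.0528 to 0.103 without treatment 3, 4 or model 1, 2, 4), osteoblast (0.0530 to 0.237 without treatment 2, 3, 4 or model 1, 3, 4), macrophage (0.0505 to 0.180 without treatment 3, 4 or model 2), T and NK cell (0.0950 without treatment 2) and oxidative phosphorylation (0.0938 to 0.655 without treatment 2 or model 2, 3). Of the 23 lists past camera 0 held with an estimated correlation, and fry called 10 of them and 1 not past camera.

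Among the osteoarthritis readouts, none of the 9 passed in treatment against model. Differences were 2.36 ± 0.98 for Mmp3, 2.13 ± 0.90 for Il6, 1.55 ± 0.83 for Acan, 1.37 ± 1.30 for Prg4, 1.12 ± 1.61 for Col2a1, 1.07 ± 0.74 for Tnf, 0.56 ± 0.35 for Adamts5, -1.0 ± 0.66 for Il1b and -1.08 ± 1.08 for Mmp13, with adjusted p of 0.141 to 0.675. Col2a1 changed sign without model 2 (-0.41).

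**Figure D3:**
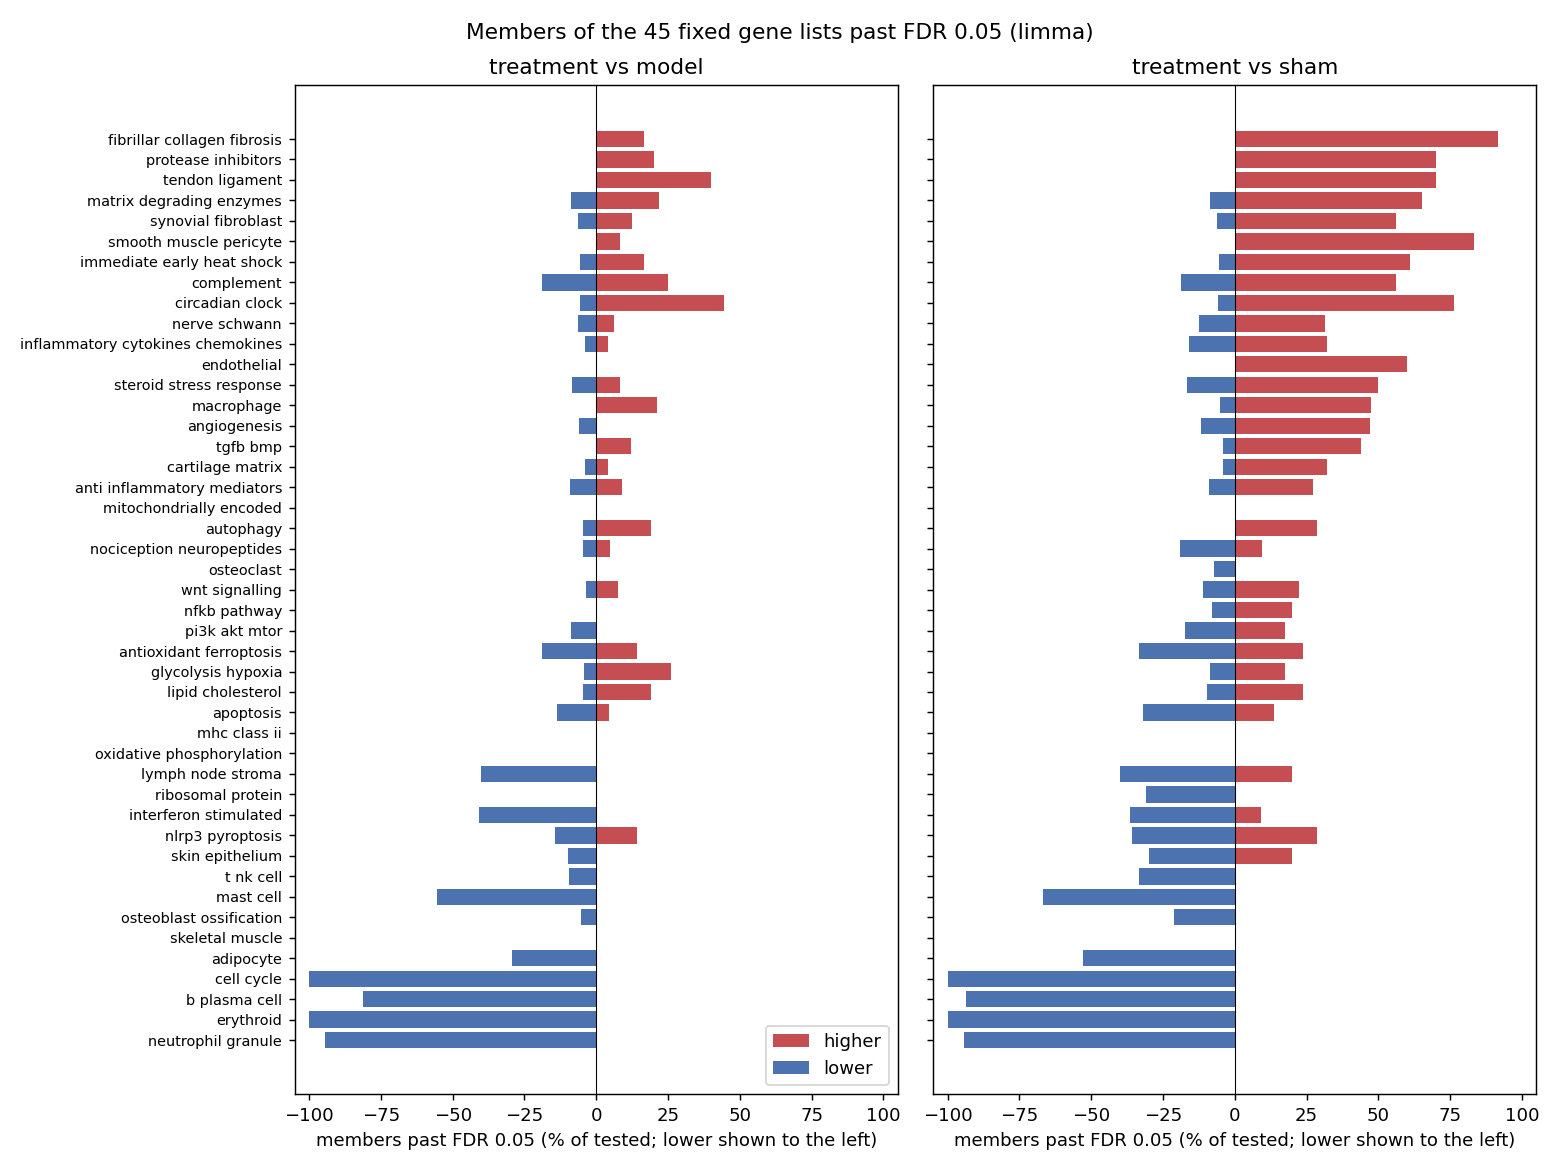
Percent of the measured members of each of the 45 fixed gene lists that passed an adjusted p of 0.05, higher to the right and lower to the left of 0, in treatment against model and treatment against sham. Erythroid and cell cycle lists reached all 18 and 22 members lower in both comparisons, and fibrillar collagen genes reached 22 of 24 higher against sham.

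Treatment against sham asks how far treated joints stood from sham joints. More genes passed than against model. Members of marrow and lymphoid lists fell and members of collagen, matrix-enzyme, fibroblast, vessel and clock lists rose, lists with adjusted p = 0.424 to 0.703 with an estimated correlation. Tnn rose by 8.11 ± 0.44 (adjusted p = 7.41e-06), from 53.7 ± 19.9 in sham to 16156 ± 10807 in treatment. Mmp12, macrophage elastase, rose by 7.98 ± 1.53, Ccl9, a chemokine of myeloid cells, by 5.95 ± 1.48, C1qtnf3 by 5.70 ± 0.75 and Msln by 5.36 ± 1.04. Nox4, a hydrogen peroxide-making oxidase, rose by 5.36 ± 0.57, Mmp3 (ENSRNOG00000032626, chromosome 8, 4640416 to 4653961) by 5.30 ± 0.61 and the matricellular Ccn5 by 5.26 ± 0.48. Among these 7, adjusted p from limma was 7.76e-05 to 0.0143. The genes that fell most were Prg2 (-11.44 ± 1.32), Prg3 (-10.89 ± 1.09), Cd177 (-10.74 ± 1.22) and Ngp (-9.96 ± 1.34). Next came Epx, eosinophil peroxidase (-9.64 ± 0.72), Mmp8 (-9.49 ± 1.07) and Ear1, an eosinophil ribonuclease (-9.32 ± 0.72). Adjusted p from limma was 2.65e-05 to 0.00103 for these 7. Rnase17, of the same ribonuclease family, had 3 reads in treatment and 3620 in sham (sham higher by a ratio of 1226, 95% counting interval 419 to 5948), and reads of this family may have been split between its members.

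Of the blood lists, erythroid genes fell in 18 of 18 (18 adjusted over the list alone), neutrophil granule genes in 17 of 18 (17 adjusted over the list alone), and B cell genes in 15 of 16 (15 adjusted over the list alone). Mast cell genes fell in 6 of 9 (6 adjusted over the list alone), T and NK cell genes in 7 of 21 (7 adjusted over the list alone) and cell cycle genes in 22 of 22 (22 adjusted over the list alone). These lists had camera adjusted p = 2.86e-16 to 0.00768, and adjusted p = 0.424 to 0.703 with an estimated correlation. Examples were Klf1 (-6.21 ± 0.47), the master regulator of red cell genes, Trim10 (-6.01 ± 0.36), Retnlg (-7.76 ± 0.49), Cxcr2 (-6.38 ± 0.32), Cd79a (-5.54 ± 0.40) and Fcrla (-4.66 ± 0.29). The other lists held Hdc (-4.33 ± 0.39), Ms4a2 (-4.78 ± 0.43), Nkg7 (-6.30 ± 0.36), Ncr1 (-5.76 ± 0.63), Birc5 (-3.61 ± 0.20) and Aurka (-3.48 ± 0.23), with limma adjusted p of 4.79e-06 to 0.000165 for all 12. The erythroid score was -4.20 ± 1.35 against 2.02 ± 0.27 in sham, the neutrophil score -4.68 ± 1.30 against 2.81 ± 0.32 and the B cell score -2.58 ± 0.34 against 1.53 ± 0.28 (exact permutation p = 0.0286, adjusted p = 0.0468 each). In all, 11 of 18 cell-type scores passed. They were these 3, mast, T and NK cell, cell cycle, adipocyte and skin scores lower, and synovial fibroblast, smooth muscle and tendon scores higher. With the median over members in place of the mean, 0 passed (smallest exact permutation p after adjustment = 0.0514). Only the skin score then left the smallest exact permutation p of 0.0286, at 0.114, and the rest of the 11 stayed there. At that floor the adjusted p depends on how many lists reach it, so the drop to 0 shows no general loss of difference. Cr2 (-5.39 ± 0.57) of B cells and Cdh1 (-4.55 ± 0.51), E-cadherin, also fell, while the desmosome gene Dsp (3.04 ± 0.60) rose.

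Collagen and fibrosis genes rose in 22 of 24 (23 adjusted over the list alone), matrix-degrading enzymes in 15 of 23 (15 adjusted over the list alone) with 2 lower, and protease inhibitors in 7 of 10 (7 adjusted over the list alone). So did tendon and ligament genes in 7 of 10 (7 adjusted over the list alone) and synovial fibroblast genes in 9 of 16 (9 adjusted over the list alone) with 1 lower. Camera gave these lists adjusted p = 2.99e-09 to 0.00115, and adjusted p = 0.424 to 0.506 with an estimated correlation. Among them were Col5a2 (2.67 ± 0.30), Col6a3 (3.35 ± 0.44), Ctsl (2.54 ± 0.27), Mmp11 (2.60 ± 0.32), Timp1 (3.10 ± 0.32) and Lum (3.21 ± 0.29), the proteoglycan lumican. Further examples were Thbs4 (2.29 ± 0.30), Pdgfra (2.31 ± 0.26) and Pdpn (3.29 ± 0.42), at limma adjusted p of 6.24e-05 to 0.000489 for these 9. The synovial fibroblast score was 0.62 ± 0.27 against -0.60 ± 0.56 in sham and the tendon score 1.22 ± 0.21 against -0.74 ± 0.79. Vessel genes rose in 10 of 12 (10 adjusted over the list alone) for smooth muscle, where edgeR called 2, and in 9 of 15 (10 adjusted over the list alone) for endothelium. They rose in 8 of 17 (8 adjusted over the list alone) for angiogenesis, where 2 fell. For these lists camera gave adjusted p = 0.000313 to 0.0174, and adjusted p = 0.506 to 0.625 with an estimated correlation. Rgs5 (2.44 ± 0.31) and Cspg4 (2.23 ± 0.33) of pericytes and Flt1 (1.54 ± 0.25), Pecam1 (1.52 ± 0.31) and Aplnr (1.98 ± 0.31) of endothelium were examples. The smooth muscle score was 0.45 ± 0.45 against -0.82 ± 0.49 in sham. TGF-beta and BMP genes rose in 11 of 25 (13 adjusted over the list alone) with 1 lower. For this list camera gave adjusted p = 0.000773, and adjusted p = 0.473 with an estimated correlation. The receptors Bmpr2 (1.47 ± 0.14) and Bmpr1a (1.37 ± 0.18) were among them.

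Clock genes rose in 13 of 17 (13 adjusted over the list alone) and 1 fell, with Bhlhe40 (2.17 ± 0.15) and Dbp (1.88 ± 0.17), an output gene of the clock. Immediate early genes rose in 11 of 18 (13 adjusted over the list alone) and 1 fell, with Klf6 (1.74 ± 0.22) and Btg2 (-1.17 ± 0.17). Steroid and stress response genes rose in 6 of 12 (6 adjusted over the list alone) and 2 fell. These lists had camera adjusted p = 9.52e-06 to 0.0380, and adjusted p = 0.424 to 0.506 with an estimated correlation. In that list Cdkn1a rose (2.63 ± 0.32) but Fkbp5, a direct glucocorticoid target, fell (-1.32 ± 0.15). Adipocyte genes fell in 9 of 17 (11 adjusted over the list alone), and osteoblast genes in 4 of 19 (0 adjusted over the list alone). Interferon-stimulated genes fell in 8 of 22 (8 adjusted over the list alone) with 2 higher, and ribosomal protein genes in 9 of 29 (7 adjusted over the list alone). Camera gave these lists adjusted p = 0.00788 to 0.0447, and adjusted p = 0.726 to 0.778 with an estimated correlation. Retn (-4.06 ± 0.68), Thrsp (-3.05 ± 0.83), Sost (-4.84 ± 1.27), Ifitm5 (-1.75 ± 0.56), Rsad2 (-5.54 ± 0.40) and Ifit1 (-3.41 ± 0.38) fell there. The adipocyte score was -1.48 ± 1.11 against 0.49 ± 0.96 in sham and the osteoblast score -1.21 ± 1.84 against 0.73 ± 0.55 (exact permutation p = 0.143). Complement genes rose in 9 of 16 (10 adjusted over the list alone) with 3 lower, and macrophage markers in 9 of 19 (9 adjusted over the list alone) with 1 lower. For these lists camera gave adjusted p = 0.00648 to 0.0187, and adjusted p = 0.650 to 0.707 with an estimated correlation. Here Msr1 (2.54 ± 0.35) rose and Cfp (-3.16 ± 0.22) and Cd163 (-1.15 ± 0.18), the haemoglobin scavenger receptor, fell.

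Several lists moved in part without passing camera. Cartilage matrix genes rose in 8 of 25 (8 adjusted over the list alone) and 1 fell (camera adjusted p = 0.108), among them Comp (3.53 ± 0.62), cartilage oligomeric matrix protein, and Cilp (1.79 ± 0.31). Without treatment 2 the cartilage list passed (0.0145), and so did the cytokine (0.0444) and Wnt lists (0.0444). The cartilage list also passed without treatment 4 (0.0403) and the nerve list without sham 1 (0.0226). Cytokine genes rose in 8 of 25 and fell in 4, with Il18 (2.18 ± 0.26) and Cxcl12 (-1.55 ± 0.14), which retains blood cells in marrow. Single regulators of inflammation, from lists that did not pass camera, went both ways. Socs3 (2.69 ± 0.25), Nfkbiz (1.29 ± 0.23) and Rela (0.56 ± 0.12) rose, and the decoy receptor Il1r2 (-5.20 ± 0.42) and Nlrc4 (-3.42 ± 0.43) fell. Of genes that act in pain sensing, P2rx7 (3.47 ± 0.48), an ATP-gated channel, and the bradykinin receptor Bdkrb2 (2.26 ± 0.40) rose. Pmp22 (2.59 ± 0.36) rose and Mbp (-1.26 ± 0.25) fell, both of myelin. Sfrp4 (4.81 ± 0.39), Fzd1 (2.66 ± 0.36), Gabarapl1 (1.61 ± 0.22), Sqstm1 (1.0 ± 0.16), Slc2a1 (2.37 ± 0.41) and Insig1 (1.54 ± 0.17) rose, and Irs2 (-0.90 ± 0.15), Gclm (-1.64 ± 0.22), Tfrc (-2.55 ± 0.43) and Hk1 (-1.39 ± 0.19) fell. Of those lists, apoptosis genes had a median of 0.01 and a mean of -0.12, and lipid genes 0.02 and -0.02, with members called in both directions.

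Of the 9 osteoarthritis readouts, 5 rose against sham. Mmp3 rose by 5.30 ± 0.61 (adjusted p = 0.000310), Prg4 (ENSRNOG00000002385, chromosome 13, 62487257 to 62504119) by 3.64 ± 1.13 (adjusted p = 0.0371) and Il6 by 3.06 ± 0.75 (adjusted p = 0.0111). Acan, aggrecan (ENSRNOG00000028992, chromosome 1, 132981582 to 133043627), rose by 2.20 ± 0.71 (adjusted p = 0.0416) and Adamts5, an aggrecan-cleaving enzyme, by 1.12 ± 0.36 (adjusted p = 0.0356). The normalised value of Mmp3 was 5536 ± 5244 in treatment and 115 ± 60.2 in sham. Il6 was at 19.0 ± 9.35 and 1.85 ± 2.61, with few reads. Its groups overlapped (0.30 CPM in treatment 1, 0.37 in sham 1), as did those of Prg4, Acan and Adamts5. Col2a1, the main collagen of cartilage, differed by 0.10 ± 1.05, Mmp13 by -0.43 ± 1.03, Il1b by -1.37 ± 0.58 and Tnf by 1.08 ± 0.71 (adjusted p = 0.0984 to 0.950). Col2a1 changed sign without treatment 1 (-1.03) and Mmp13 with edgeR (0.58).

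limma called 7485 of 20352 genes, 3524 higher and 3961 lower. edgeR called 7265, DESeq2 8491 and limma-voom 10003. Without sham 2, sham 4 and treatment 2 it called 4598, and with the marrow score as a covariate 2. Of 94 named genes 90 passed, and 76 of these kept the call in every alternative that tested them, apart from the covariates and a 2-fold requirement. The block ended 1 of the calls, edgeR 2 and the muscle covariate 1. The marrow covariate ended all 90, of which 78 kept their sign. In some alternative 3 other named genes gained a call. Adjusted p without 1 library exceeded 0.05 for Sost (0.0589 without treatment 4), Ifitm5 (0.0688 to 0.0906 without treatment 2, 3, 4 or sham 1, 2, 3, 4), Thrsp (0.0502 to 0.0604 without treatment 3 or sham 1) and Acan (0.0625 to 0.102 without treatment 1, 3, 4 or sham 1, 2, 3, 4). Adamts5 (0.0791 to 0.0966 without treatment 1, 3 or sham 2, 3, 4) and Prg4 (0.0755 to 0.0965 without treatment 1, 2, 3 or sham 2, 3, 4) lost the call too. By camera, calls ended for interferon-stimulated (0.0579 to 0.154 without treatment 1 or sham 1, 3, 4), osteoblast (0.0579 to 0.121 without treatment 2, 3, 4 or sham 1, 4), macrophage (0.0504 without treatment 3) and steroid and stress response (0.0531 to 0.0649 without treatment 1 or sham 1, 3). Of the 24 lists past camera 0 held with an estimated correlation, and fry called 21 of them and 2 not past camera.

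The design also asks whether treatment turned back what the model changed. With limma no gene passed in model against sham, so 0 genes could be counted as reversed (2618 had an unadjusted p under 0.05). Leaving out model 1 gave 2 reversed genes and leaving out sham 3 gave 1. DESeq2 counted 102 of its 288 genes as called in the opposite direction in treatment against model and 56 in the same direction, where independent lists of these sizes would share 37.0 and 34.6. limma-voom counted 40 opposite and 415 in the same direction, where independent lists would share 166 and 158. Both comparisons use the model libraries with opposite sign, which by itself makes fold changes look reversed. Across 19785 genes, which are not independent replicates, the correlation of the fold changes was 0.07, against -0.51 in 20 simulations without effects. The covariance was 0.0763 against -0.165, a difference of 0.242. The correlation turned to -0.07 without model 2. edgeR gave -0.03, with -0.17 to 0.09 over its settings (covariance -0.336 to 0.110), and DESeq2 -0.17 (covariance -0.319), on other scales than the simulations. With the model libraries split 2 and 2 between the comparisons, the covariance ranged from -0.182 to 0.773 over 6 splits, with a mean of 0.241. Opposite signs were seen in 39.7% of genes, against 67.0% simulated.

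The authors' deposited table of changed genes listed 422 for model against sham (175 higher, 247 lower). It listed 3363 for treatment against model (1108 and 2255) and 5704 for treatment against sham (2886 and 2818). Those lists hold the genes of the authors' deposited table with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. limma called 0, 2301 and 5263 of the genes listed in the authors' deposited table. Of those in the authors' deposited table for model against sham, 407 had an unadjusted limma p under 0.05, and DESeq2 on the 12 libraries called 218. Of the 247 genes lower in model in the authors' deposited table, 20 belong to the skeletal muscle list, which has 26 members there. By the authors' deposited table, 124 of the 422 were also listed for treatment against model, 76 with the opposite sign and 48 with the same sign, where independent lists would share 30.5 and 34.2. Of the 76, 69 were lower in model and higher in treatment, and 7 were the other way round. The lists are not independent, since both comparisons use the model libraries with opposite sign, which by itself adds opposite signs.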

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

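The 2 tests on the labels of model 1 and sham 1 were chosen after the result was seen, and the tests of muscle genes outside the fixed list and of other splits of the libraries before.

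A library stands here because its gap to the nearest of the other 3 libraries of its group is a larger share of the group's range than Dixon's 95% critical value for 4 values. That happened 28 times in 534 groups of values tested, and chance does so in about 1 in 20 groups. Where the other 3 libraries are all at 0, any read sets the flag, so that rate does not hold. This applies to Asb16 and Lbx1 in model 1 and to Ear1 and Rnase17 in treatment 3. Values are log2(CPM + 1), with the range of the other 3 libraries behind them. In model 1 the B cell score was 1.92 against 0.75 to 0.79, and the genes were Cdkn1a (3.15 against 3.71 to 3.73), Socs3 (3.82 against 5.01 to 5.24), Asb16 (0.0901 against 0.00) and Lbx1 (0.17 against 0.00). In model 2 they were Lyz2 (11.01 against 12.33 to 12.37) and Ldha (8.19 against 8.68 to 8.73). Sham 1 stood apart for Prg4 (9.84 against 6.92 to 7.29), Kdr (6.25 against 5.58 to 5.65), Skil (5.59 against 6.18 to 6.29) and Gabarapl1 (6.51 against 5.51 to 5.60). Sham 3 did so for Col2a1 (9.12 against 10.28 to 10.41), Mmp8 (10.60 against 9.89 to 9.97), S100a9 (12.82 against 12.13 to 12.23) and the unnamed gene model on chromosome 4 (0.52 against 0.00 to 0.09), and sham 4 for Mcm2 (7.38 against 7.75 to 7.79) and Btg2 (7.54 against 7.16 to 7.204). Treatment 1 stood apart for Ifitm5 (3.64 against 1.501 to 1.62). Treatment 2 did so for Asb16 (4.13 against 0.16 to 0.56), Cd177 (2.38 against 0.00 to 0.38), Col6a3 (9.72 against 11.25 to 11.37), Irs2 (4.87 against 5.32 to 5.36) and Hk1 (5.97 against 6.71 to 6.86). Treatment 3 did so for Ear1 (0.61 against 0.00) and Rnase17 (0.23 against 0.00), and treatment 4 for Vsig4 (1.83 against 5.32 to 5.99), Igll1 (0.00 against 0.95 to 1.03) and Cr2 (0.72 against 0.16 to 0.17).

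Model 1 resembled sham: after centring, it correlated with sham 2 to 4 at a mean of 0.25 and with model 2 to 4 at -0.35, a difference of 0.603. A wrong label of model 1 alone and a weak response of that sample predict the same values, so the 2 cannot be told apart. A piece with more muscle may resemble sham as well, which was not tested apart. The muscle score of model 1 was 0.27, against -4.36 to -3.32 in model 2 to 4 and 0.91 to 4.27 in sham. An exchange with sham 1 stays open too. Sham 1 correlated at a mean of -0.0453 with sham 2 to 4 and -0.118 with model 2 to 4. These 2 means, both below 0, differ by 0.0732 only. The real split of these 8 libraries gave 0 limma calls, a count that all 35 splits reach whatever the data, so it says nothing of chance. Among the others, model 1 with sham 2 to 4 against the rest gave the most, so an exchange of the labels of sham 1 and model 1 takes the count from 0 to 1694, which does not decide whether the labels are wrong. Muscle genes outside the fixed list were lower in model as well, at a median log2 fold change of -4.01 with 14 of 14 members lower, as differing amounts of muscle in the pieces predict, and a biological loss of muscle in model joints predicts it too and was not tested.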

How the results depend on the processing

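Alternatives chosen after seeing the data were edgeR on recovered reads with its settings, values rescaled by TMM, the fit without the 3 muscle-rich libraries and the fit without muscle and blood-cell list genes. In model against sham, limma called 0 genes (2618 at unadjusted p under 0.05), and so did every alternative (edgeR 0) except DESeq2 (288), limma-voom (817) and the fits without model 1 (169), sham 3 (28) or model 4 (2), a range of 0 to 169 without 1 library. In treatment against model, 2870 became 5756 with DESeq2, 6645 with limma-voom, 0 with the marrow covariate (546 at unadjusted p under 0.05) and 1170 (without model 4) to 4138 (without model 2) without 1 library. In treatment against sham, 7485 became 4598 without the muscle-rich libraries, where fewer samples were tested, and 2 with the marrow covariate. The other settings kept these counts within 1.5 times. Reversed genes numbered 0, but 102 with DESeq2, 40 with limma-voom, 2 at most with the model libraries split 2 and 2, and 0 to 2 without 1 library (2 without model 1, 1 without sham 3). Lists past camera fell to 0 in each comparison with an estimated correlation. Fry called 1 list in model against sham and 11 in treatment against model, of which 10 had passed camera, and without the muscle-rich libraries camera called 12 in model against sham. Cell-type scores past the exact test in treatment against sham became 0 with medians, where only the skin score left the smallest exact p. The marrow score of each treatment library lies below those of all 8 others, so that covariate shares most of its information with the groups. In model against sham, the muscle score of each model library likewise lies below those of all sham libraries. For the other changes the cause was not tested. At this depth and with 4 libraries per group, 2-fold changes were recovered in 3% to 7% of simulated genes.

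Same numbers gave no clear pairing of the libraries. Of 12 same-number pairs, 4 correlated above 0.1 (from -0.57 to 0.35), and in 5 of the 12 the first library correlated best with its own number among the 4 of the other group. This does not show that the libraries are unpaired, since muscle content enters these correlations. The highest pair, sham 2 and treatment 2, are both rich in muscle transcripts. With the replicate number as a block the counts were 0, 2204 and 6771, the antioxidant list had a camera direction opposite to its median of 0.0231 in treatment against model, and in the edgeR fit with the block in treatment against sham Col2a1 was at -0.20 and Mmp13 at 0.00860.

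The following values changed sign, or for lists the direction of the test, with none past the test after the change, and the cause was not tested. With the muscle covariate in model against sham they were Mmp12 -0.58, Timp1 -0.36, C1r -0.77, Pdgfrb -0.42, Igll1 0.0571, Emcn -0.24, Kdr -0.0278, Des 0.0336, Tgfbr2 -0.22, Klf6 -0.17, Egr2 -0.13, Cox6a2 0.83, Mcm5 0.14, Mcm2 0.39, Errfi1 -1.16, Col2a1 1.63, Adamts5 -0.89, Il1b 0.49, Il6 -1.56 and Prg4 -0.54. With the marrow covariate they were Col2a1 0.15 in model against sham, in treatment against model Msln -0.0411, C1qtnf3 -1.67, Stmn2 -0.18, Prg2 3.02, Ngp 2.01, S100a9 0.0569, S100a8 0.0545, Ctsg 5.28, Timp2 -0.17, Phex 0.64, Cd14 -0.76, Trem2 -1.65, Ms4a2 0.0836, Sfrp4 -0.72, Dkk3 -0.75, Chrd -0.66, Skil -0.0406, Slc2a1 -0.86, Insig1 -0.62, Mmp3 -0.94, Adamts5 -0.38 and Tnf -0.53, and in treatment against sham Mmp12 -3.80, Ccl9 -5.20, Prg2 1.73, Ngp 3.47, Cilp -0.62, Cdh1 0.32, Dsp -0.20, Cdkn1a -0.18, Tfrc 0.0662, Klf6 -0.37, Slc2a1 -1.14, Col2a1 -1.09, Acan -0.17 and Tnf -3.89. On recovered reads, Col2a1 in model against sham was 0.12, 0.13 and 0.14 with edgeR and 0.12 with DESeq2. Mmp13 in treatment against sham was 0.52, 0.54, 0.58 and 0.59 with edgeR, 0.54 with DESeq2 and 0.40 with limma-voom, where Col2a1 was -0.25. The muscle covariate gave Mmp13 0.0320 in treatment against model and Col2a1 -0.79 in treatment against sham. Without the muscle-rich libraries Tnf was -0.61 in model against sham. For treatment against model that fit left out treatment 2 only, so it is the same as the fit without that library. In treatment against model the NLRP3 list -0.19, the apoptosis list 0.0165 and the oxidative phosphorylation list -0.0329 were the medians, and in treatment against sham the NLRP3 list -0.46, the apoptosis list 0.17, the lipid list -0.21 and Mmp13 0.49 were the values. The antioxidant list had a fry direction opposite to its medians of 0.0231 in treatment against model and 0.0440 in treatment against sham. With medians over members, the osteoclast score differed by 0.0139 and the smooth muscle score by -0.0124 in treatment against model. Leaving out 1 library gave ranges, in model against sham, of the cell cycle list -0.61 to 0.0452, Col2a1 -1.64 to 0.53 and Tnf -0.30 to 0.35. In treatment against model they were the NLRP3 list -0.43 to 0.00670, the apoptosis list -0.10 to 0.0190, the antioxidant list -0.0141 to 0.14, the oxidative phosphorylation list -0.0329 to 0.54 and Col2a1 -0.41 to 1.77, and in treatment against sham the apoptosis list -0.13 to 0.0946, the antioxidant list 0.0232 to 0.19, Col2a1 -1.03 to 0.72 and Mmp13 -1.18 to 0.60.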

Other observations

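The tests on library size, bone, dilution and scaling were chosen after the result was seen, and those on stem and megakaryocyte genes and on other splits of the libraries before. Single clock, platelet and stem cell genes are named here after their values were seen.

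Clock genes did not move as one. Targets of clock activators were higher in treatment than in sham for Dbp (1.88, limma adjusted p = 6.20e-05), Nr1d1 (1.81, adjusted p = 0.000275), Nr1d2 (1.76), Tef (1.51), Hlf (1.75), Per2 (1.25) and Per3 (1.07), and so were the activators Npas2 (2.65) and Clock (0.92). Per1 was at 0.56 (limma adjusted p = 0.112), Bmal1 at 0.67 (adjusted p = 0.1002) and Cry1 at -0.48 (adjusted p = 0.257), none past the test. Nfil3, which represses Dbp targets, fell (-1.87, adjusted p = 0.000220). Against model, Nr1d1 (1.73), Dbp (1.85) and Ciart (1.90) rose and Per2 was at 0.78 (adjusted p = 0.137). Hours of collection are not stated in the labels.

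Treatment libraries differed among themselves. Cartilage scores were 1.91 in treatment 1 and -0.60 to 0.25 in the others, and osteoblast scores 1.36 and -2.94 to -1.25. Cytokine scores were 1.07 in treatment 3 and 1.77 in treatment 4, against -0.43 in treatment 1 and -0.60 in treatment 2. MHC class II scores were -1.66 in treatment 2 and 1.14 in treatment 3. Platelet and megakaryocyte genes, in none of the fixed lists, fell in 9 of 9 against sham (median -4.88) and in 8 of 9 against model (median -3.81), with Ppbp at -8.32 ± 1.06 against sham.

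For the fall of marrow genes in treatment, a difference in library size is excluded, with a largest ratio of group mean read totals of 1.05. The test of less marrow assumes that only marrow cells make the genes it uses, which was not tested. Less marrow in the treatment pieces predicted that megakaryocyte and stem cell genes outside the lists fall too. Megakaryocyte genes did (median -4.88), but stem cell genes had a median of -0.435, above the bound of -0.5 set to exclude it, with 4 lower, such as Myb (-6.79 ± 0.67) and Gfi1 (-5.98 ± 0.71), and Mecom higher (1.58 ± 0.35). The bound was not cleared by more than the spread (lower quartile -1.74), a requirement added after the value was seen, so less marrow stays a possible explanation that the data do not decide. The osteoblast score gave an exact permutation p of 0.143 for less bone in the pieces, and a biological loss of marrow cells under treatment cannot be told from a difference in dissection.

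For the rise of matrix genes in treatment, dilution by marrow loss alone predicts that endothelial, nerve, smooth muscle and skin lists rise as much. In 2 of these 4 the matrix score gained more than that, with means and with medians over members. The matrix score gained 3.02 on the skin score and 1.41 on the endothelial one (exact permutation p = 0.0286 each, 0.0381 adjusted over 4 lists and 0.0571 with medians). The gain on the nerve score was 1.55 (exact permutation p = 0.0286 with means and 0.0857 with medians). On the smooth muscle score it was 1.01 (exact permutation p = 0.114 with both). The test assumes that marrow makes none of the genes in these lists, which was not tested, and Cdh1 of the skin list fell along with the marrow genes. Dilution is therefore not excluded, in part or as the whole cause. Scaling of the libraries cancels in the matrix score minus the median of all genes of the same library, which was 2.47 higher in treatment (exact permutation p = 0.0286), so it is excluded as the cause. A change of fibroblasts or of matrix expression under treatment, and a different mix of fibrous tissue in the pieces, were not tested apart. Of the 35 splits of the 8 libraries, 1 gave as many genes as treatment against model, the real one (2870). The same count, 1 of 35, held for treatment against sham (7485), with 0 genes as the highest of the others in both. The other splits mix the groups, which raises the spread within each side and lowers their counts. Chance assignment of the libraries is thus unlikely but not excluded, since 1 of 35 is the smallest share that 4 against 4 can give.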
